A study of Homo sapiens with 14 samples.

How the data were processed

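RNA sequencing was used to profile 293 Flip-In T-REx cells, a human embryonic kidney line that carries a single site for inserting a transgene. Per the labels, the lines held either an empty vector (ctrl) or a SNAP-ADAR transgene. A SNAP-ADAR is a fusion of the SNAP tag, an engineered form of the protein encoded by MGMT, to the deaminase domain of ADAR (SA1) or of ADARB1 (SA2). The tag bonds covalently to a benzylguanine-modified guide RNA, which directs the deaminase to a transcript for adenosine-to-inosine editing. SA1Q and SA2Q carry a glutamine in place of a glutamate of the deaminase domain, a change known to raise the activity of the enzyme. The 14 libraries fall into 7 groups of 2, which are ctrl, SA1Q, SA2Q, SA1Q+gRNA, SA2Q+gRNA, SA1+gRNA and SA2+gRNA. The design text of the series speaks of 2 biologically independent experiments. The target of the guide and any induction of the transgene are not given in the sources used here.

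Per the labels' protocols, total RNA was treated with DNase I, polyadenylated RNA was selected, libraries were prepared with a kit that keeps strand information, and sequencing was paired-end. Per the submitters' processing notes, Trim Galore, STAR 2.4.2a and the build hg19 were used, with no role or order stated. The tool that counted fragments, its use of strand and its handling of fragments with several matches are not given in the sources used here. Genes that overlap a neighbour, lie antisense to one, or have near-identical copies are therefore uncertain. Each of the 14 files held 3 measured columns for 46830 RefSeq transcripts. The count column held whole numbers of fragments per transcript, deposited without normalization per the file headers. The FPM column held the same fragments scaled to the library total and was used only to recover the library total. The FPKM column was, per the file headers, the count scaled by the authors to transcript size and library total, and it served only in an alternative. All coordinates are those of the files, on hg19 and counted from 1.

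Transcript accessions were matched to gene symbols with a RefSeq gene table of assembly GRCh38.p14, used for names only, and then with a GENCODE table. Of the 45595 accessions, 44381 were named by the first table and 565 by the second, together 98.6%, and 649 were not named. The 887 entries without a name held 0.81% of the counts on average and stayed out of library sizes and tests. A further 2309 named entries lay under a minimum size of 200 nucleotides and were left out. Transcripts of a gene share fragments, so each gene was represented by its transcript with the highest mean FPM, which gave 22395 genes, 13282 of them with 1 transcript. Genes with enough counts by filterByExpr (minimum count 10, at least 2 libraries) numbered 16407. At an unadjusted p under 0.05, chance alone would give 820 of them in each comparison.

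Library totals ran from 43.0 to 130.1 M fragments, and the genes analysed held 93.2% to 95.0% of them. SA1+gRNA replicate 2 had the highest total. All of its 40542 counts above 0 were even numbers, 100%, against 47.7% to 48.7% in the other libraries, for which the sources used here give no reason; counted by pairs, its depth is 65.1 M. The common biological coefficient of variation was 8.7%, on 7 residual degrees of freedom. With 2 libraries per group, each SD rests on a pair of values.

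Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, quasi-likelihood fit and test, two-sided), over all 14 libraries so that the groups shared an estimate of the spread, with no covariate. P-values were adjusted by the Benjamini-Hochberg method within each of the 14 comparisons, and genes with an adjusted p under 0.05 were called. The design written before the data were examined held a branch for FPKM and a branch for counts, and the second was used because the files held counts. Per-library levels are TMM-scaled counts on the usual CPM scale, given as mean ± SD with n = 2, and log2 changes are given with their standard error (SE). Every adjusted p for a gene below is from edgeR's quasi-likelihood test unless another tool is named.

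The groups, the comparisons, the tests, the rule for named genes and the gene lists were fixed before the data were examined. ADAR, ADARB1 and MGMT were named in every comparison. In the 4 main comparisons (SA1Q and SA2Q against ctrl, and each with against without guide), the 10 genes with the largest rise and the 10 with the largest fall were named, and in the others 5 each way. A named gene had to be called, to have non-overlapping libraries in the groups compared, and to reach a mean of 1 CPM in the higher group. Clone names were left out, and 1 gene that met the rule is not reported here. Of each list, up to 4 called members with the smallest p were named, or 2 where none was called, with ACTB, GAPDH and GUSB in every case. A gene named beyond these rules is said to have been chosen after its values were seen.

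Of 24 lists, 23 had at least 3 tested members. They were adenosine deaminases, interferon-stimulated genes, nucleic acid sensors and cytokines, the integrated stress response, the unfolded protein response, p53 targets, cholesterol synthesis, immediate early genes, heat shock, edited transcripts, housekeeping transcripts, S phase, G2 and mitosis, replication-dependent histones, nuclear-encoded oxidative phosphorylation (OXPHOS), ribosomal proteins, glycolysis and hypoxia, oxidative and metal stress, nuclear-retained RNAs, neuronal-lineage genes, and fibroblast, epithelial and blood cell markers as signs of other cell types. The epithelial list held keratins abundant in every library, so it turned out not to single out other cells. The list of mitochondrially encoded genes had no measured member and was not analysed here. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison. The same test with an estimated correlation and fry were run beside it. The adenosine deaminase list holds the parents of the transgenes, so its result in a transgenic line is not independent of the construct.

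The gene and list tests were first run on simulated data made from these libraries for SA1Q against ctrl, in 3 runs of 16198 genes with 200 changed. They recovered 62.2% of changes of 1.5-fold, 78.1% of 2-fold and 90.4% of 4-fold, and 5.7% of calls were false. An unchanged comparison, SA2Q against ctrl, gave at most 0 calls. A list raised 1.3-fold had an adjusted p of 6.1e-62 by camera, and 1 other list was also called. Genes were drawn independently, with the same spread in every group and no library that deviated as a whole. These rates may therefore not hold for the real libraries, and the list result does not check the preset correlation. A length trend was planted in 1 library, and its slope measured over 16184 genes went from -0.182 before the length and GC correction to 0.002 after it.

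Other settings chosen in advance were no filter on low counts, median-of-ratios size factors, the replicate number as a block, a fit of only the groups compared, each library left out in turn, DESeq2 1.42.0 and, for lists, an estimated correlation. Another pseudocount applies to FPKM only and was not run. Chosen after the data had been examined were 5 more, which were the counts of SA1+gRNA replicate 2 halved, the pair of libraries that stood apart left out, the longest transcript of each gene, limma on log2(FPKM + 0.1) for genes with FPKM of at least 1 in at least 2 libraries, and an offset for transcript length and GC content (lowess span 0.3). Comparisons with the same ctrl libraries share their chance values, so overlaps are set beside 20 simulated sets of unchanged groups and beside the overlap of independent lists. RNA editing itself cannot be read from counts per transcript and was not analysed here. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.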

Results

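Transcript levels were measured by polyadenylated RNA sequencing in 14 libraries of 293 Flip-In T-REx cells, 2 for each of 7 groups. The series was designed to find off-target editing in SNAP-ADAR cell lines, and the comparisons below ask how transcript levels differed between the same groups. Library totals were 45.2 and 55.1 M fragments for ctrl, 56.9 and 49.4 M for SA1Q, 50.5 and 62.2 M for SA2Q, and 43.0 and 63.5 M for SA1Q+gRNA. They were 66.5 and 68.2 M for SA2Q+gRNA, 58.1 and 130.1 M for SA1+gRNA, and 47.0 and 65.9 M for SA2+gRNA. The 10 most abundant genes took 3.78% to 4.93% of the counts of a library. Replicates correlated across genes with Pearson's r of 0.9844 in ctrl, 0.9859 in SA1Q+gRNA and 0.9932 to 0.9946 in the other groups, where genes are not independent replicates.

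Transcripts of the enzyme parents followed the labels in every library. ADAR, which encodes an RNA adenosine deaminase (chromosome 1, 154554534 to 154580724, minus strand), was at 324 ± 23 CPM in ctrl (SD, n = 2). It stood at 1093 ± 10 in SA1Q, 1229 ± 130 in SA1Q+gRNA and 1515 ± 130 in SA1+gRNA, rises of 1.75, 1.92 and 2.23 on the log2 scale (SE 0.09 each; adjusted p = 8.2e-08, 2.3e-08 and 3.2e-09, edgeR). The SA2 lines held 322 ± 13 (SA2Q), 303 ± 8.9 (SA2Q+gRNA) and 320 ± 13 CPM (SA2+gRNA). ADARB1, a second editing enzyme (chromosome 21, 46494493 to 46646478, plus strand), was at 33.3 ± 5.6 CPM in ctrl and rose to 1010 ± 99 in SA2Q, 1162 ± 2 in SA2Q+gRNA and 974 ± 12 in SA2+gRNA. Those rises were 4.92, 5.12 and 4.87 on the log2 scale (SE 0.13 each; adjusted p = 3.1e-12, 1.9e-12 and 3.5e-12, edgeR), and the SA1 lines stayed between 27.8 ± 3.2 and 31.8 ± 0.84 CPM. Counts of ADAR and ADARB1 do not separate the transgene from the endogenous gene. MGMT, the DNA repair gene behind the SNAP tag (chromosome 10, 131265454 to 131565783, plus strand), was not called in any comparison and lay at 17.5 ± 0.31 CPM in ctrl and from 14.4 ± 0.053 (SA1Q) to 21.4 ± 2.1 CPM (SA2+gRNA) in the other groups.

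**Figure D1:**
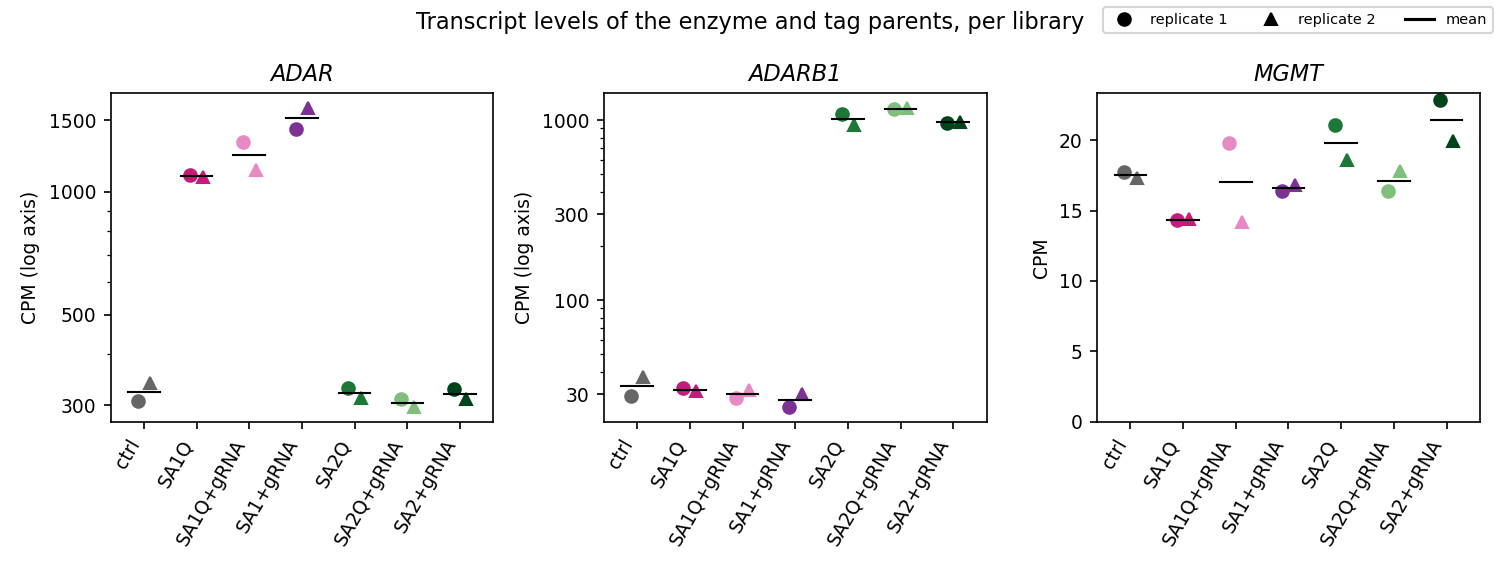
ADAR and ADARB1 (log axes) and MGMT (linear axis from 0) in CPM for each library, with circles for replicate 1, triangles for replicate 2 and bars for group means. ADAR is raised in the 3 SA1 groups (means of 1093 to 1515 against 324 in ctrl) and ADARB1 in the 3 SA2 groups (974 to 1162 against 33.3).

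A pair of libraries stood apart from the other 12. The first principal component took 24.8% of the variance and placed ctrl replicate 1 at -43.6 and SA1Q+gRNA replicate 1 at -47.7, with the rest between 0.4 and 14. They were the shallowest libraries, and the log2 differences between replicates had an SD of 0.54 in ctrl and 0.52 in SA1Q+gRNA, against 0.32 to 0.37 elsewhere. These differences correlated with transcript length across genes (Spearman's rho -0.37 in both groups) and with GC content (0.21 in ctrl and 0.53 in SA1Q+gRNA). In the other groups rho was -0.03 to 0.19 with length, and with GC content it was larger in size than in ctrl in SA1+gRNA (-0.43), SA1Q (-0.36) and SA2Q+gRNA (-0.32), so a GC trend was not particular to these libraries. The pre-ribosomal RNA RNA45SN5, which lacks a poly(A) tail, ran from 2372 CPM to 11993 CPM and was highest in SA1Q+gRNA replicate 1, whereas ctrl replicate 1 held 4108 and ctrl replicate 2 6332 CPM. Of the genes of the lists, chosen after their values were seen, the collagen gene COL6A3 stood at 2.53 CPM in ctrl replicate 1 and 2.24 in SA1Q+gRNA replicate 1, against 0.105 to 0.406 in the other 12. The glutamate receptor genes GRIA2 (0.908 and 0.566 against at most 0.125) and GRIA4 (0.74 and 0.54 against at most 0.162) were also highest in these libraries. On the second component the 4 libraries of the SA1Q line lay at 17.2 to 24.7 and the other 10 at -21.4 to -1.7. Every comparison with ctrl or SA1Q+gRNA holds 1 of the libraries that stood apart, and SA1Q+gRNA against ctrl holds both, on opposite sides.

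**Figure D2:**
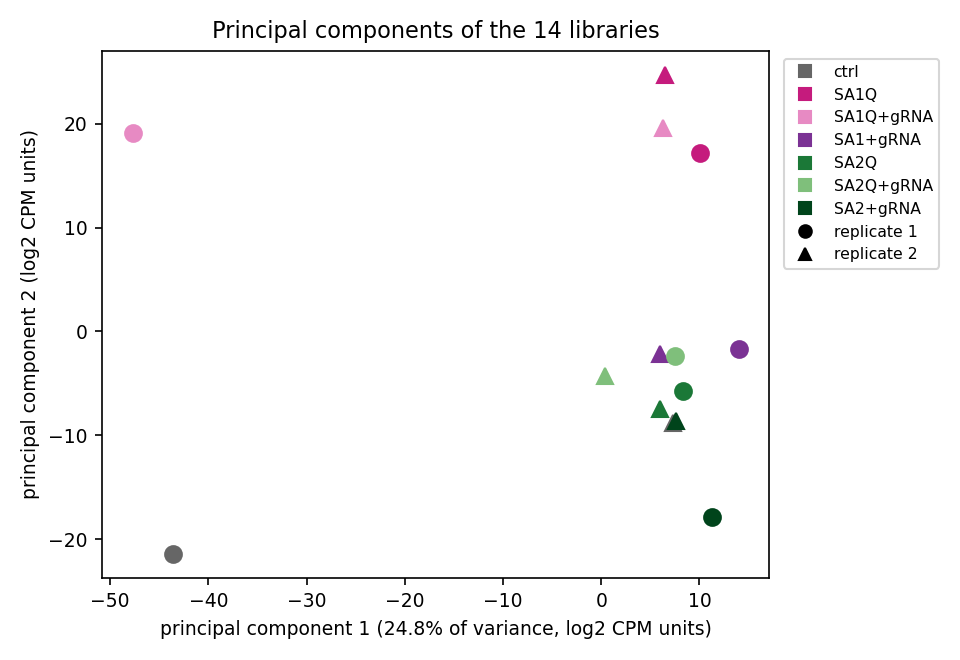
Scores of the 14 libraries on the first 2 principal components of log2 CPM, coloured by group, with circles for replicate 1 and triangles for replicate 2. ctrl replicate 1 and SA1Q+gRNA replicate 1 lie at -43.6 and -47.7 on the first component, and the 4 SA1Q-line libraries lie above 17 on the second.

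The line with SA1Q was compared with ctrl to see which transcripts differed where this enzyme was expressed without a guide. PTPRZ1, a receptor phosphatase of neural and glial cells (chromosome 7, 121513159 to 121702090, plus strand), rose from 1.25 ± 0.35 to 5.68 ± 0.1 CPM (log2 change 2.16, SE 0.26, adjusted p = 0.0017, n = 2 per group, edgeR). CPLX2, a complexin of synaptic vesicle release (chromosome 5, 175298501 to 175311023, plus strand), rose by 1.54 on the log2 scale (SE 0.2, adjusted p = 0.002), and UNC13A, which primes synaptic vesicles (chromosome 19, 17712137 to 17799008, minus strand), by 1.06 (SE 0.17, adjusted p = 0.0077). The largest fall was in ISL1, a LIM-homeodomain transcription factor (chromosome 5, 50678958 to 50690563, plus strand), from 2.07 ± 0.051 to 0.0564 ± 0.049 CPM (log2 change -5.08, SE 0.59, adjusted p = 0.0014). CHAC1, a glutathione-degrading enzyme induced by ATF4 (chromosome 15, 41245636 to 41248717, plus strand), fell from 7.15 ± 1 to 2.64 ± 0.15 CPM (log2 change -1.43, SE 0.18, adjusted p = 0.0018).

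In all, 459 of 16407 genes were called in SA1Q against ctrl, 174 higher and 285 lower, and 49 of them changed more than 2-fold. With the length and GC offset the balance turned, with 564 of 970 called genes higher and the rest lower. Other named rises were the zinc finger gene ZNF257 (log2 change 1.87, SE 0.22), the glutamate receptor gene GRIK3 (1.15, SE 0.19), PHF21B (1.14, SE 0.15), TRIM67 (1.36, SE 0.34), the long non-coding RNA TUNAR (1.14, SE 0.26) and MFAP2, a microfibril protein gene (1.04, SE 0.22). Named falls were CHRDL1, a BMP antagonist (-2.83, SE 0.47), SLITRK5 (-2.68, SE 0.5), the ephrin receptor gene EPHA5 (-1.88, SE 0.28), the lymphatic growth factor gene VEGFC (-1.83, SE 0.25), TEX19 (-1.49, SE 0.25), NOS3 (-1.46, SE 0.24), PTCHD1 (-1.45, SE 0.36) and the interferon-induced BST2 (-1.4, SE 0.3). EPHA5, NOS3 and ISL1 overlap antisense or neighbouring genes, so their counts are uncertain. MGMT had a log2 change of -0.29 (adjusted p = 0.24). The count was 315 without ctrl replicate 1 and 825 without ctrl replicate 2, and it fell to 39 without SA1Q replicate 1 and 38 without SA1Q replicate 2. Of the 20 genes named for the largest rises and falls, only ADAR, PTPRZ1, ZNF257, CPLX2, PHF21B, ISL1 and CHAC1 passed in each of these fits.

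Among the gene lists, ribosomal proteins and targets of the integrated stress response were lower in SA1Q than in ctrl. Of 37 ribosomal protein genes, 36 had changes below 0, 6 were called lower and 25 were lower when adjusted over the list alone (median log2 change -0.28, adjusted p = 9.4e-13 by camera). RPS9 fell by 0.67, RPL3 by 0.63, RPL4 by 0.39 and RPL10A by 0.34 on the log2 scale, and their many pseudogene copies make these counts uncertain. With an estimated correlation the list was not called (adjusted p = 0.35 with an estimated correlation). Of 35 integrated stress response genes, 9 were called lower and 1 higher, and 17 were lower and 1 higher adjusted over the list alone (median -0.32, adjusted p = 1.4e-09 by camera; adjusted p = 0.06 with an estimated correlation). Besides CHAC1 these included the cystine transporter gene SLC7A11 (-0.9, adjusted p = 0.0023, edgeR), the serine synthesis gene PHGDH (-0.53) and the amino acid transporter gene SLC7A5 (-0.61). SLC7A11 overlaps an antisense transcript. At the preset correlation the list was called without each of the 4 libraries.

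Interferon-stimulated genes were also lower in SA1Q, with 4 of 35 called lower and 12 adjusted over the list alone (median -0.21, adjusted p = 0.00023 by camera; adjusted p = 0.06 with an estimated correlation). They were IFI35 (-0.98, adjusted p = 0.02, edgeR), BST2, IFIT1 (-0.91, adjusted p = 0.03) and OAS3 (-0.69). Sensors and cytokines had 1 of 22 called lower, STING1 (-0.48), and 1 adjusted over the list alone (median -0.3, adjusted p = 0.0068 by camera; adjusted p = 0.06 with an estimated correlation), and it missed the threshold without ctrl replicate 1 (adjusted p = 0.067) and without both libraries that stood apart (0.083). Immediate early genes had 2 of 23 called lower, MYC (-0.58) and BTG2 (-0.37), and 4 adjusted over the list alone (median -0.26, adjusted p = 0.00024 by camera; adjusted p = 0.35 with an estimated correlation). Oxidative and metal stress genes had 0 of 14 called by edgeR and 5 lower adjusted over the list alone (median -0.2, adjusted p = 0.00023 by camera; adjusted p = 0.35 with an estimated correlation). MT1F, of a family of near-identical metallothioneins, had a change of -1.46 (adjusted p = 0.051), and OSGIN1 of -0.75 (adjusted p = 0.052).

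Epithelial and fibroblast markers, listed in advance as signs of other cell types, lay lower in SA1Q than in ctrl. Over the 14 libraries KRT8 ran from 231 to 349 CPM and KRT19 from 68.8 to 97.7 CPM. With these keratins abundant in every library, the epithelial list does not single out RNA of other cells. Its change is therefore not read as a change in their amount. Of 11 epithelial markers, 8 lay below 0, KRT19 (-0.46, adjusted p = 0.0083, edgeR) and KRT8 (-0.48, adjusted p = 0.017) were called lower, and 5 were lower and 1 higher adjusted over the list alone (median -0.27, adjusted p = 0.0036 by camera; adjusted p = 0.06 with an estimated correlation). KRT8 overlaps KRT18. Of 11 fibroblast markers, 10 lay below 0, COL1A1 fell by 0.64, and 2 were lower adjusted over the list alone (median -0.58, adjusted p = 0.0053 by camera; adjusted p = 0.12 with an estimated correlation); without SA1Q replicate 2 the list missed the threshold (adjusted p = 0.091). COL6A3, a member of this list, was at 2.53 CPM in ctrl replicate 1, 0.227 in ctrl replicate 2, and 0.256 and 0.236 in SA1Q. Blood cell markers had 0 of 9 called, 7 below 0 and 1 lower adjusted over the list alone (median -0.3, adjusted p = 0.15; CD68 -0.57, LCP1 -0.21). The deaminase list was called higher through ADAR (adjusted p = 0.0015 by camera; adjusted p = 0.06 with an estimated correlation), with 1 of 5 called, 1 higher and 1 lower adjusted over the list alone, a median of -0.03 against a mean of 0.21, and no call without a filter on low counts (adjusted p = 0.34).

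The other lists were not called in SA1Q against ctrl. Heat shock had 2 of 15 called higher, DNAJA1 (0.36) and HSPA8 (0.36), and 3 higher and 1 lower adjusted over the list alone (median 0.07, mean -0.03, adjusted p = 0.3). Cholesterol synthesis had 2 of 26 called lower, TM7SF2 (-0.56, overlapping VPS51 and uncertain) and INSIG1 (-0.39), and 4 adjusted over the list alone (median -0.07, adjusted p = 0.15). Glycolysis and hypoxia had 2 of 30 called lower, PFKL (-0.47) and NDRG1 (-0.71), and 4 adjusted over the list alone (median -0.07, adjusted p = 0.15). Neuronal-lineage genes had 1 of 18 called higher, INA (0.47), and 4 higher and 2 lower adjusted over the list alone (median -0.01, mean -0.08, test upward, adjusted p = 0.56). The p53 targets had 1 of 20 called lower, BTG2, with 2 higher and 3 lower adjusted over the list alone (median -0.02, adjusted p = 0.67). S phase genes had 1 of 28 called lower, CDT1 (-0.6), and 1 adjusted over the list alone (median 0.01, mean -0.03, adjusted p = 0.67). OXPHOS genes had UQCRC2 called higher (0.3) and ATP5F1D lower (-0.74) of 32, the same numbers adjusted over the list alone, and a median of 0 with a mean of -0.01 (test upward, adjusted p = 0.67). Nuclear-retained RNAs had PSPC1 called lower (-0.3) of 6, and 2 adjusted over the list alone (median -0.13, adjusted p = 0.15).

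Lists with 0 genes called in SA1Q against ctrl by edgeR, over all genes and adjusted over the list alone, were edited transcripts (28 genes, median -0.04, adjusted p = 0.67), housekeeping transcripts (16, median -0.05, adjusted p = 0.84), G2 and mitosis (28, median -0.03, adjusted p = 0.32) and histones (24, median 0.21, adjusted p = 0.34). The unfolded protein response had 0 of 22 called and 1 lower adjusted over the list alone (median -0.01, adjusted p = 0.67). Members with the smallest p were CYFIP2 (0.29, overlapping FNDC9) and COPA (0.2, overlapping NCSTN and uncertain) among edited transcripts, UBE2C (-0.29) and TACC3 (-0.26) in mitosis, and H2BC21 (0.68) and H2BC11 (-1.17) among histones. H2BC11 was at 7.64 CPM in ctrl replicate 1 and 1.61 in ctrl replicate 2, against 1.86 and 2.19 in SA1Q, so its direction rested on ctrl replicate 1. GRIA2 and GRIA4, of the edited transcripts, were highest in the same ctrl library. ACTB had a change of -0.11, GAPDH of -0.04 and GUSB of -0.16. Histone transcripts mostly lack a poly(A) tail and were measured after poly(A) selection.

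The line with SA2Q was compared with ctrl in the same way. Besides ADARB1, the largest rise was in ZNF257 (chromosome 19, 22235266 to 22273903, plus strand), from 0.716 ± 0.1 to 2.92 ± 0.34 CPM (log2 change 2.03, SE 0.21, adjusted p = 0.00085, n = 2 per group, edgeR). The calcium-release channel gene RYR2 (chromosome 1, 237205702 to 237997288, plus strand) rose from 7.02 ± 0.15 to 16.4 ± 0.48 CPM (1.23, SE 0.17, adjusted p = 0.012), and MFAP2 (chromosome 1, 17300999 to 17307173, minus strand) from 2.09 ± 0.55 to 5.11 ± 0.29 (1.27, SE 0.21, adjusted p = 0.041). ISL1 fell to 0.19 ± 0.091 CPM (-3.4, SE 0.48, adjusted p = 0.012), and CHRDL1 (chromosome X, 109917084 to 110039286, minus strand) fell by 3.19 (SE 0.49, adjusted p = 0.019).

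In SA2Q against ctrl 14 genes were called, 9 higher and 5 lower (2 and 4 by limma, 12 and 16 without ctrl replicate 2). Other rises were PRXL2A (0.8, SE 0.13), the nitric oxide synthase gene NOS2 (0.78, SE 0.12), the T-type calcium channel gene CACNA1H (0.75, SE 0.1) and TMCO4 (0.59, SE 0.1), and further falls were the snoRNA host genes SNHG3 (-0.77, SE 0.13) and SNHG12 (-0.62, SE 0.11). SNHG3, SNHG12 and CACNA1H overlap other genes and are uncertain. The count was 8 without ctrl replicate 1, 28 without ctrl replicate 2, and 2 without either SA2Q library. Of the 13 genes that met the naming rule, 3, 9, 2 and 2 passed in those fits, and ADARB1 and ZNF257 passed in each; ISL1 had an adjusted p of 0.32 without SA2Q replicate 1 and 0.25 without SA2Q replicate 2.

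Among lists in SA2Q against ctrl, the unfolded protein response lay higher, with 20 of 22 genes above 0 and 0 called by edgeR (median 0.08, adjusted p = 0.016 by camera; adjusted p = 0.58 with an estimated correlation). PDIA4 had a change of 0.22 and DNAJB11 of 0.23. Immediate early genes lay lower, with 0 of 23 called and 1 adjusted over the list alone (median -0.2, adjusted p = 0.0013; adjusted p = 0.58 with an estimated correlation; MYC -0.44, JUN -0.24). Both lists missed the threshold without ctrl replicate 1 (adjusted p = 0.08 each), and the first without SA2Q replicate 1 (0.074) and without both libraries that stood apart (0.069). Ribosomal proteins had 0 called, also adjusted over the list alone (median -0.07, adjusted p = 0.016; adjusted p = 0.74 with an estimated correlation); the list turned upward without ctrl replicate 1 (adjusted p = 0.04) and without both libraries that stood apart (0.023). The deaminase list was called through ADARB1 (median -0.01, mean 0.93, adjusted p = 2.2e-28; adjusted p = 0.00019 with an estimated correlation). The integrated stress response had a median of -0.08 (adjusted p = 0.062). ACTB, GAPDH and GUSB had changes of -0.02, -0.01 and -0.03.

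**Figure D3:**
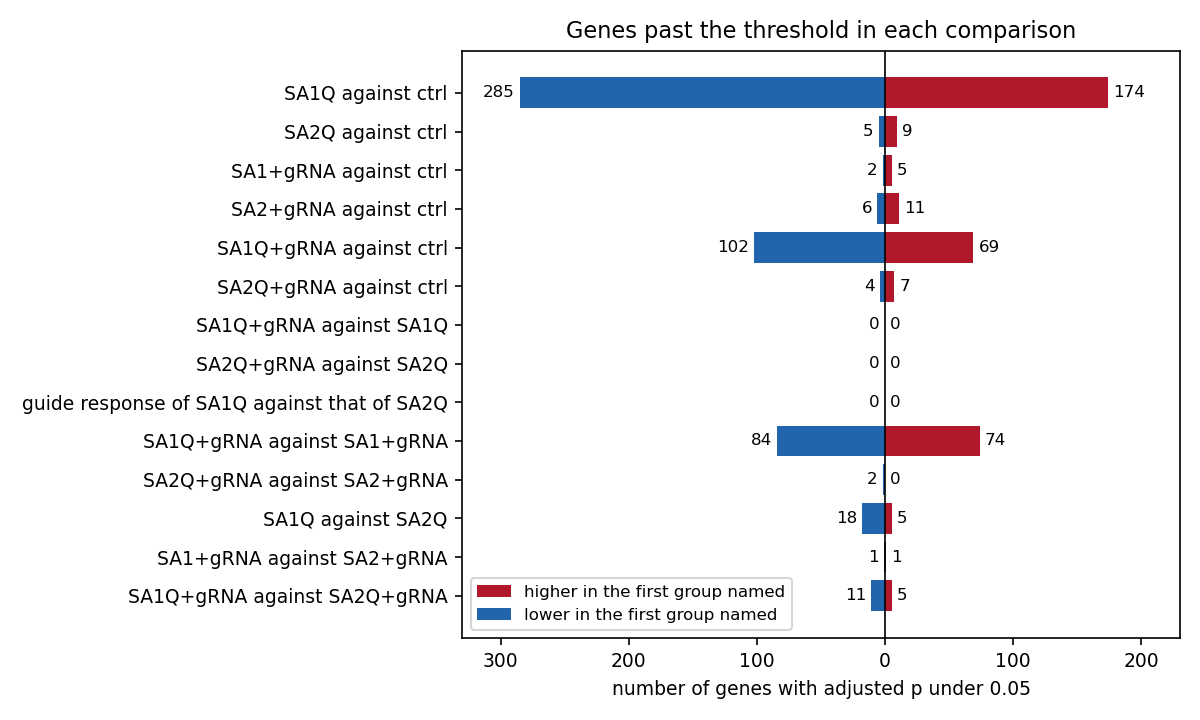
Number of genes called lower (left) and higher (right) in each of the 14 comparisons, at an adjusted p under 0.05 by edgeR. Of the counts drawn, SA1Q against ctrl has the most, 285 lower and 174 higher, and the 3 guide comparisons have 0. With the length and GC offset, not drawn, 564 of 970 were higher in SA1Q against ctrl, and SA1Q+gRNA against ctrl had more calls, 995.

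Cells with a guide were compared with cells of the same line without one, which asks what the guide changed. No gene was called for SA1Q or for SA2Q. ADAR had a change of 0.17 in SA1Q (adjusted p = 0.43, edgeR), and ADARB1 of 0.2 in SA2Q (adjusted p = 1). In SA1Q, all 23 immediate early genes lay above 0 with the guide, 0 were called by edgeR, and the list was called higher (median 0.2, adjusted p = 0.00035 by camera; adjusted p = 0.79 with an estimated correlation). In SA2Q, 20 of the 23 lay above 0 (median 0.09, adjusted p = 0.0014; adjusted p = 0.83 with an estimated correlation). ATF3 had changes of 0.24 and 0.26 in these comparisons, JUN 0.23 in SA1Q and DUSP1 0.27 in SA2Q.

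The gene counts with against without guide were 0 by edgeR, DESeq2 and limma in SA1Q, with 2004 genes at an unadjusted p under 0.05 (smallest adjusted p = 0.39, MZF1, which overlaps MZF1-AS1 and was chosen after its values were seen). In SA2Q they were 0 by the 3 tools, with 291 genes at an unadjusted p under 0.05 (smallest adjusted p = 1). That is fewer than the 820 of chance alone, so the test was probably conservative for this pair. The 0 does not show that the guide changed nothing, and a fit of only these groups called 1 gene higher and 9 lower. Without SA1Q+gRNA replicate 2, which leaves the library that stood apart, the SA1Q count was 2114; it was 0 without each of the other three libraries, and the SA2Q count was 0 in all 4 such fits. The test of the difference between the guide responses called 0 genes by edgeR, DESeq2 and limma (929 at an unadjusted p under 0.05, smallest adjusted p = 0.71) and 0 lists (smallest adjusted p = 0.13, S phase). The responses correlated across genes with r = 0.11.

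Other lists moved with the guide by small amounts. Ribosomal proteins lay higher in SA1Q (34 of 37 above 0, median 0.11, adjusted p = 0.00035 by camera; adjusted p = 0.79 with an estimated correlation; RPL13 0.4, RPS19 0.31) and in SA2Q (34 of 37, median 0.06, adjusted p = 0.0016; adjusted p = 0.83 with an estimated correlation). Epithelial markers lay lower in SA2Q (10 of 11 below 0, median -0.09, adjusted p = 0.0014; adjusted p = 0.1 with an estimated correlation; CLDN7 -0.79, KRT19 -0.21). S phase genes (median 0.04, adjusted p = 0.032; adjusted p = 0.58 with an estimated correlation) and nuclear-retained RNAs (6 of 6 above 0, median 0.05, adjusted p = 0.034; adjusted p = 0.56 with an estimated correlation; MALAT1 0.46, NEAT1 0.31) lay higher in SA2Q. All these lists had 0 genes called by edgeR, also adjusted over the list alone. In SA1Q, the immediate early list missed the threshold without SA1Q replicate 1 (adjusted p = 0.061) and SA1Q+gRNA replicate 1 (0.22), and the ribosomal list without SA1Q+gRNA replicate 1 (0.56). Without both libraries that stood apart they had adjusted p-values of 0.19 and 0.42, and with the length and GC offset the ribosomal list turned downward (adjusted p = 0.66 by camera). In SA2Q, the immediate early list missed it without SA2Q replicate 2 (0.18) and SA2Q+gRNA replicate 2 (0.092), nuclear-retained RNAs without SA2Q replicate 2 (0.33) and SA2Q+gRNA replicate 1 (0.41), and S phase without SA2Q replicate 2 (0.78), SA2Q+gRNA replicate 1 (0.052) and SA2Q+gRNA replicate 2 (0.17). Without a filter on low counts these last lists had adjusted p-values of 0.39 and 0.051.

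SA1+gRNA and SA2+gRNA were compared with ctrl, which holds the line and the guide together. NCAN, a brain proteoglycan gene (chromosome 19, 19322782 to 19363061, plus strand), rose from 0.404 ± 0.098 CPM in ctrl to 7.55 ± 2.6 in SA1+gRNA (log2 change 4.21, SE 0.37, adjusted p = 6.8e-05, n = 2 per group, edgeR) and 6.4 ± 0.8 in SA2+gRNA (3.96, SE 0.37, adjusted p = 0.00019). ALDH1L2, a mitochondrial folate enzyme gene regulated by ATF4, rose in SA1+gRNA from 2.6 ± 1.1 to 8.43 ± 0.87 CPM (1.67, SE 0.22, adjusted p = 0.0058) and in SA2+gRNA by 1.51 (adjusted p = 0.017). ISL1 fell in both (-3.32, SE 0.45, adjusted p = 0.0058, and -3.47, SE 0.49, adjusted p = 0.0087). CEBPE, a myeloid transcription factor gene, fell in SA2+gRNA from 58.8 ± 3.3 to 26.5 ± 4.1 CPM (-1.15, SE 0.13, adjusted p = 0.0019).

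Of 7 genes called in SA1+gRNA against ctrl, 5 were higher, also MFAP2 (1.9, SE 0.21) and RYR2 (1.37, SE 0.17), and 2 were lower; DESeq2 gave 43 higher and 58 lower. Of 17 in SA2+gRNA, 11 were higher and 6 lower (6 and 10 without ctrl replicate 1), also the zinc finger genes ZNF738 (4.4, SE 0.62) and ZNF257 (1.82, SE 0.22), MFAP2 (1.58, SE 0.21), PTCHD1 (-2.41, SE 0.39), EPHA5 (-1.71, SE 0.28), the potassium channel gene KCND1 (-1.04, SE 0.17) and the neurofilament gene NEFL (0.75). For SA1+gRNA the count was 11 without ctrl replicate 1, 22 without ctrl replicate 2 and 4 without SA1+gRNA replicate 1; ISL1 then missed the threshold without SA1+gRNA replicate 1 (adjusted p = 0.25) and replicate 2 (0.16), and ALDH1L2 without SA1+gRNA replicate 1 (0.11). For SA2+gRNA it was 16 without ctrl replicate 1, 29 without ctrl replicate 2, 2 without SA2+gRNA replicate 1 and 11 without SA2+gRNA replicate 2, and of its 12 named genes 7, 8, 2 and 7 passed with ctrl replicates 1 and 2 and SA2+gRNA replicates 1 and 2 left out in turn, ADARB1 and NCAN in each.

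Targets of the integrated stress response lay higher in both groups against ctrl, and the unfolded protein response was called in SA1+gRNA. There the unfolded protein response had a median of 0.19 with 0 genes called by edgeR, also adjusted over the list alone (adjusted p = 1.2e-05 by camera; adjusted p = 0.42 with an estimated correlation; HERPUD1 0.27), against a median of 0.06 in SA2+gRNA (adjusted p = 0.29). The integrated stress response had ALDH1L2 called in both, with 2 and 5 of 35 genes higher adjusted over the list alone (medians 0.08 and 0.12, adjusted p = 0.0014 and 6.2e-05; adjusted p = 0.42 and 0.62 with an estimated correlation). Glycolysis and hypoxia had 0 called, with 0 and 2 higher adjusted over the list alone (medians 0.1 and 0.15, adjusted p = 0.0066 and 3.7e-05; adjusted p = 0.5 and 0.71 with an estimated correlation; MXI1 0.46 and VEGFA 0.33 in SA2+gRNA). Immediate early genes lay lower with 0 called (medians -0.16 and -0.26, adjusted p = 0.034 and 0.0079; adjusted p = 0.52 and 0.71 with an estimated correlation). Ribosomal proteins lay higher with 0 called (median 0.08 in both, adjusted p = 0.0046 and 0.0092; adjusted p = 0.65 and 0.78 with an estimated correlation).

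SA1Q+gRNA and SA2Q+gRNA were compared with ctrl in the same way. In SA1Q+gRNA, ZNF738 rose by 4.47 (SE 0.62, adjusted p = 0.003, edgeR), NCAN by 2.37 (SE 0.41, adjusted p = 0.013) and CPLX2 to 6.02 ± 0.8 CPM (1.59, SE 0.2, adjusted p = 0.0016), and ZNF257 rose by 1.49 (SE 0.22). ISL1 (-4.31, SE 0.54), CHRDL1 (-3.46, SE 0.51), SLITRK5 (-3.23, SE 0.53), PTCHD1 (-1.96, SE 0.37) and EPHA5 (-1.82, SE 0.28) fell. In SA2Q+gRNA, ZNF257 (2.01, SE 0.21), MFAP2 (1.23, SE 0.21), RYR2 (1.15, SE 0.17) and TVP23A, which overlaps NUBP1 (0.7, SE 0.12), rose, and ISL1 (-4.2, SE 0.51), CHRDL1 (-2.98, SE 0.46) and EPHA5 (-1.73, SE 0.27) fell. The calls numbered 171 (69 higher, 102 lower; 524 and 471 with the length and GC offset) and 11 (7 higher, 4 lower; 5 and 0 by limma). The first was 224 without ctrl replicate 1 (116 higher, 108 lower) and 463 without SA1Q+gRNA replicate 2 (241 and 222), and the second 6 without ctrl replicate 1, 13 without ctrl replicate 2 (6 and 7) and 2 without either SA2Q+gRNA library. NCAN missed the threshold in SA1Q+gRNA without ctrl replicate 1 (adjusted p = 0.053). Of the 26 named genes in SA1Q+gRNA, 20, 18, 19 and 23 passed without ctrl replicates 1 and 2 and SA1Q+gRNA replicates 1 and 2, and of 8 in SA2Q+gRNA 3, 5, 2 and 2 passed in the like fits, ADARB1 and ZNF257 in each. PTCHD1 missed it in SA1Q+gRNA without ctrl replicate 2 (0.057) and SA1Q+gRNA replicate 1 (0.081).

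Interferon-stimulated genes were lower in SA1Q+gRNA than in ctrl, with IFI35 the only gene called (-0.91) and 8 of 35 lower adjusted over the list alone (median -0.24, adjusted p = 8.5e-08 by camera; adjusted p = 0.017 with an estimated correlation). Epithelial markers were lower too, with KRT19 (-0.46) and CLDN7 (-1.67, overlapping ELP5) called of 11 and 4 adjusted over the list alone (median -0.36, adjusted p = 1.1e-05; adjusted p = 0.017 with an estimated correlation). The integrated stress response had 7 of 35 called lower, and 12 lower and 2 higher adjusted over the list alone (median -0.19, adjusted p = 4.9e-08; adjusted p = 0.062 with an estimated correlation), among them CHAC1 (-1.03), SLC7A11 (-0.85), STC2 (-0.56) and ASNS (-0.53). The neuronal-lineage genes SYP (0.57, overlapping the antisense SYP-AS1), INA (0.45) and CHGA (0.95) rose, and their list was not called (adjusted p = 0.073). IFI35 missed the threshold without ctrl replicate 1 (adjusted p = 0.12, edgeR) and without either SA1Q+gRNA library (0.051 and 0.091), and ASNS without ctrl replicate 1 (0.06). Without ctrl replicate 2, SYP, INA, CHGA, STC2 and CLDN7 missed it (0.11, 0.11, 0.12, 0.079 and 0.067), and without SA1Q+gRNA replicate 1, SYP, CHGA and STC2 (0.099, 0.14 and 0.095). CHGA was at 10.5 CPM in that library and 6.83 in SA1Q+gRNA replicate 2. In SA2Q+gRNA the unfolded protein response had a median of 0.13 with 0 called by edgeR, also adjusted over the list alone (adjusted p = 0.002; adjusted p = 0.59 with an estimated correlation).

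Several genes were called in many of the 6 comparisons with ctrl. ISL1 was lower in all 6, MFAP2 and RYR2 were higher in all 6, ZNF257 was higher in 5 and CACNA1H in 4, and CHRDL1 and EPHA5 were lower in 4. In SA2Q and SA2Q+gRNA against ctrl, ISL1, MFAP2 and RYR2 did not keep the call in every fit with 1 library left out, whereas ZNF257 did. In 20 simulated sets of unchanged groups and controls, drawn with the same spread in every group, a gene was called in at most 2. SA1Q and SA2Q shared 5 higher and 4 lower genes, where independent lists would share 0.1 and 0.09 and the simulation gave 0 of each. Their changes correlated across genes with r = 0.68, against 0.51 in the simulation, and had a covariance of 0.123 against 0.0416. SA1Q and SA1Q+gRNA shared 43 higher and 83 lower genes (0.73 and 1.77 for independent lists), with r = 0.55 against a simulated 0.5 and a covariance of 0.0871 against 0.0412. SA1Q+gRNA and SA2Q+gRNA shared 4 higher and 4 lower genes (0.03 and 0.02 for independent lists), and their r of 0.46 lay below the simulated 0.52, with a covariance of 0.0635 against 0.0414. The covariance was 0.122 for SA1+gRNA and SA2+gRNA (simulated 0.0418) and 0.126 for SA2Q and SA2Q+gRNA (simulated 0.0412). The ctrl group of 2 libraries could not be split. Replicates differed more in ctrl (SD of the log2 differences 0.54) than in the other groups (0.52 in SA1Q+gRNA, 0.32 to 0.37 elsewhere), which the simulation leaves out. The simulated values are thus no bound, and part of the excess or all of it may come from the shared controls.

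**Figure D4:**
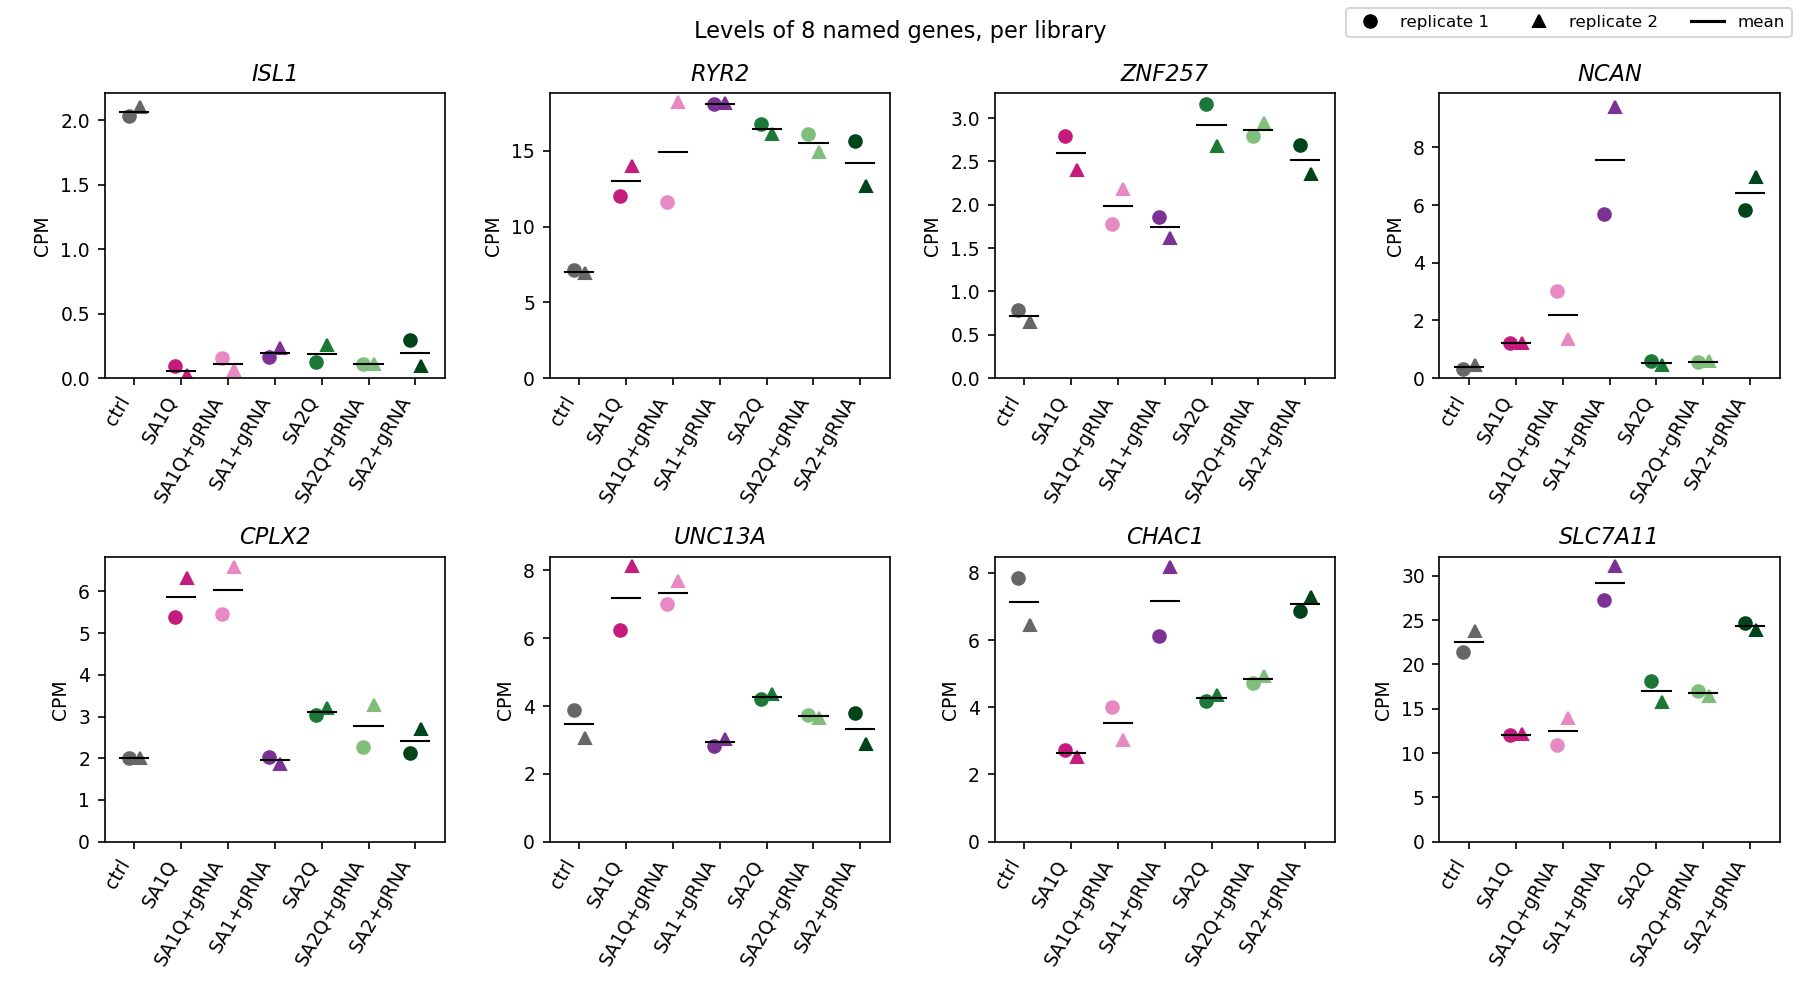
CPM of 8 named genes in each library (linear axes from 0), with circles for replicate 1, triangles for replicate 2 and bars for group means. ISL1 is above 2 CPM in both ctrl libraries and below 0.3 in the other 12, CPLX2 and UNC13A are highest in the 4 SA1Q-line libraries, and NCAN is highest in SA1+gRNA and SA2+gRNA.

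The Q enzymes were compared with the enzymes without that change, both with guide. They were held by different lines, so line and Q change differed together. SLC7A11 (chromosome 4, 139085248 to 139163503, minus strand) was lower in SA1Q+gRNA than in SA1+gRNA, at 12.5 ± 2.2 against 29.2 ± 2.7 CPM (log2 change -1.22, SE 0.12, adjusted p = 0.00029, n = 2 per group, edgeR), and ALDH1L2 at 3.12 ± 0.15 against 8.43 ± 0.87 (-1.43, SE 0.22, adjusted p = 0.0088). CPLX2 was higher, at 6.02 ± 0.8 against 1.95 ± 0.12 CPM (1.64, SE 0.19, adjusted p = 0.00062), as were UNC13A (1.32, SE 0.17, adjusted p = 0.0015) and the secretogranin gene SCG3 (1.29, SE 0.14, adjusted p = 0.00058). NCAN was lower in both comparisons, by -1.84 in SA1Q+gRNA (SE 0.29, adjusted p = 0.0098) and by -3.47 in SA2Q+gRNA (0.576 ± 0.025 against 6.4 ± 0.8 CPM; SE 0.34, adjusted p = 0.00057). The proton-gated channel gene ASIC1 (chromosome 12, 50451420 to 50477405, plus strand) was lower in SA2Q+gRNA than in SA2+gRNA (25.7 ± 0.41 against 40.2 ± 1.5 CPM; -0.65, SE 0.09, adjusted p = 0.019).

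In SA1Q+gRNA against SA1+gRNA 158 genes were called, 74 higher and 84 lower. The balance moved to 347 higher and 242 lower by DESeq2, 224 and 156 without a filter on low counts, and 59 and 161 without both libraries that stood apart. Other named genes were the homeobox gene NKX6-2 (1.87, SE 0.37), WFIKKN1 (1.71, SE 0.35), RAB26 (-1.4, SE 0.23) and KLHDC8A (-1.39, SE 0.27). ADAR had a change of -0.3 (adjusted p = 0.11). The count was 17 without SA1+gRNA replicate 1, 29 without SA1+gRNA replicate 2, 58 without SA1Q+gRNA replicate 1 and 2083 without SA1Q+gRNA replicate 2 (1225 higher, 858 lower), and of 27 named genes 8, 11, 15 and 26 passed, CPLX2, UNC13A, SCG3 and SLC7A11 in each. NCAN missed the threshold without SA1+gRNA replicate 2 (adjusted p = 0.12). In SA2Q+gRNA against SA2+gRNA only NCAN and ASIC1 were called, both lower (4 genes higher and 29 lower with the length and GC offset), with 1291 genes at an unadjusted p under 0.05. Without SA2+gRNA replicate 2 the count was 5, and without each of the other three it was 1. NCAN passed in each such fit and ASIC1 in none (adjusted p = 0.58 and 0.054 without SA2+gRNA replicates 1 and 2, and 0.86 and 0.38 without SA2Q+gRNA replicates 1 and 2). ADARB1 had a change of 0.25 (adjusted p = 0.58).

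The integrated stress response was lower with the Q enzyme in both pairs. In SA1Q+gRNA 12 of 35 genes were called lower and 16 adjusted over the list alone (median -0.29, adjusted p = 4e-17 by camera; adjusted p = 0.028 with an estimated correlation), with SLC7A11, ALDH1L2, the asparagine synthetase gene ASNS (-0.81, adjusted p = 0.0012, edgeR) and the serine synthesis gene PSAT1 (-0.6, adjusted p = 0.0012). In SA2Q+gRNA 0 were called by edgeR, and 11 were lower and 2 higher adjusted over the list alone (median -0.21, adjusted p = 5.2e-09; adjusted p = 0.28 with an estimated correlation; PSAT1 -0.44, DDIT4 -1.08). Cholesterol synthesis genes were lower in SA1Q+gRNA, with INSIG1 (-0.76), MSMO1 (-0.59) and IDI1 (-0.45) called of 26, and 7 lower and 1 higher adjusted over the list alone (median -0.19, adjusted p = 3e-06; adjusted p = 0.028 with an estimated correlation). IDI1 overlaps IDI2-AS1. Ribosomal proteins had 5 of 37 called lower in SA1Q+gRNA and 23 adjusted over the list alone (median -0.23, adjusted p = 3.4e-12; adjusted p = 0.38 with an estimated correlation; RPL3 -0.48).

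Neuronal-lineage genes were higher in SA1Q+gRNA than in SA1+gRNA, with SYP (0.76, overlapping SYP-AS1) and CHGA (1.21) called of 18 and 4 adjusted over the list alone (median 0.35, adjusted p = 0.00038 by camera; adjusted p = 0.12 with an estimated correlation). The unfolded protein response had HERPUD1 called lower (-0.51) and 7 of 22 adjusted over the list alone (median -0.2, adjusted p = 1.4e-05; adjusted p = 0.28 with an estimated correlation), and interferon-stimulated genes had IFIT1 (-0.94), 1 of 35 either way (median -0.21, adjusted p = 0.00026; adjusted p = 0.11 with an estimated correlation). Glycolysis and hypoxia genes had NDRG1 called lower in SA1Q+gRNA (-0.89), with 5 of 30 adjusted over the list alone (median -0.12, adjusted p = 0.00024; adjusted p = 0.38 with an estimated correlation), and 0 called in SA2Q+gRNA by edgeR, with 2 adjusted over the list alone (median -0.19, adjusted p = 3.4e-07; adjusted p = 0.51 with an estimated correlation). Without SA1Q+gRNA replicate 2 the former had an adjusted p of 0.16, and without SA2+gRNA replicate 1 the latter had 0.19. Histone transcripts lay higher in both (medians 0.39 and 0.37, adjusted p = 0.0022 and 0.00026; adjusted p = 0.38 and 0.51 with an estimated correlation), with 0 called by edgeR, and 3 and 0 adjusted over the list alone.

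**Figure D5:**
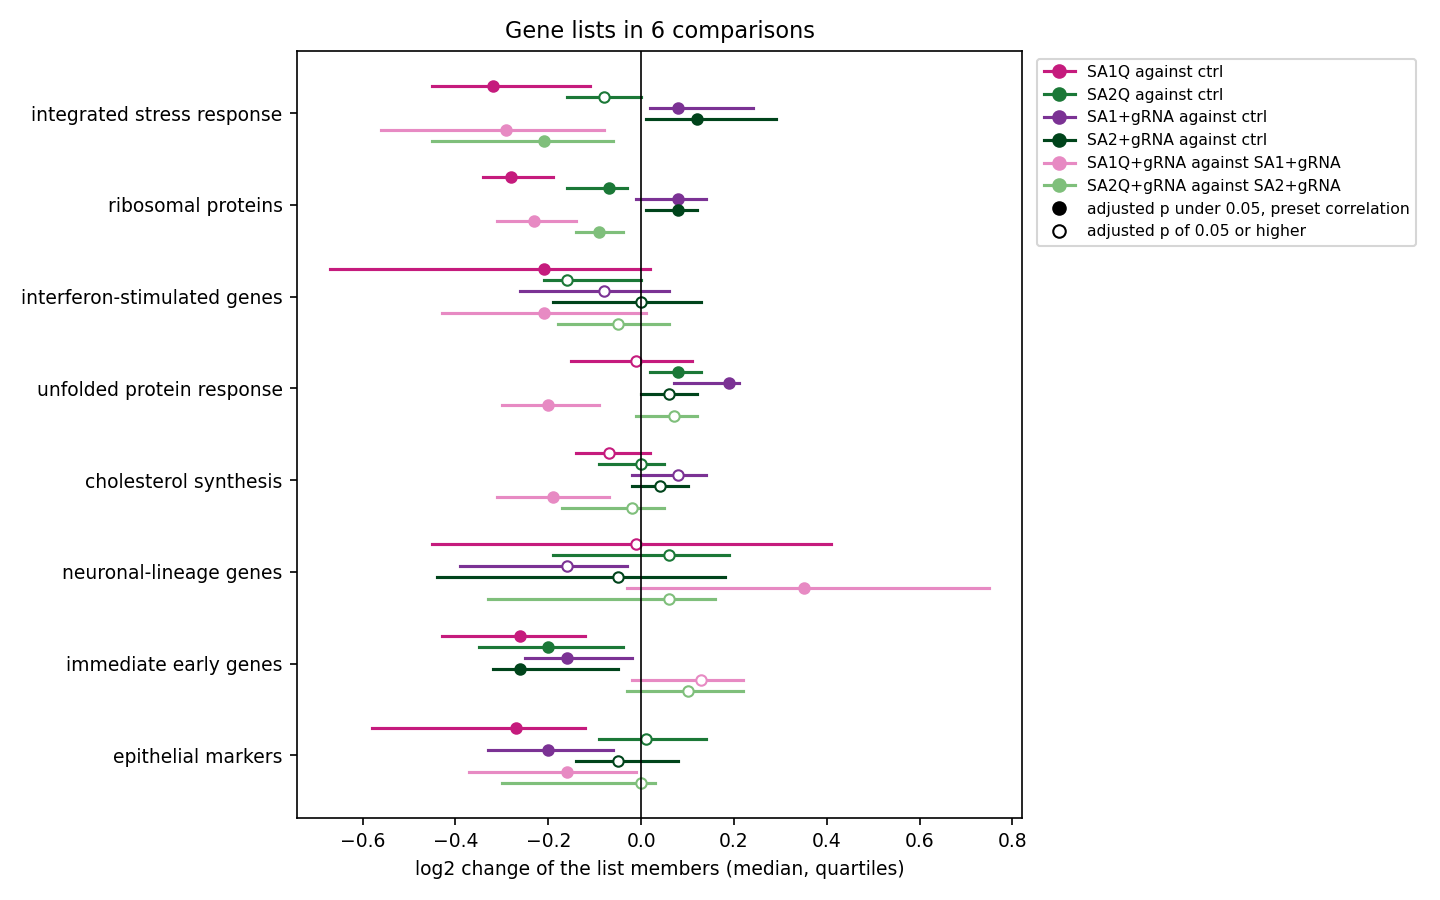
Median (points) and quartiles (lines) of the log2 changes of the members of 8 gene lists in 6 comparisons, filled where the adjusted p at the preset correlation is under 0.05. The integrated stress response lies at -0.32 in SA1Q against ctrl, at -0.29 and -0.21 in the comparisons of Q with non-Q enzymes, and at 0.08 and 0.12 in SA1+gRNA and SA2+gRNA against ctrl.

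The ADAR and ADARB1 constructs were compared with each other. IFRD1, an interferon-related regulator gene (chromosome 7, 112090483 to 112117258, plus strand), was higher in SA1Q than in SA2Q, at 178 ± 0.71 against 107 ± 1.6 CPM (log2 change 0.74, SE 0.08, adjusted p = 0.0011, n = 2 per group, edgeR), and higher with guide, at 169 ± 8.5 against 115 ± 2.2 (0.56, SE 0.08, adjusted p = 0.031). The translation factor gene EIF5 was higher in SA1Q, at 426 ± 4.2 against 283 ± 6.4 CPM (0.59, SE 0.09, adjusted p = 0.022), and the scavenger receptor gene SCARA5 lower, at 10.7 ± 0.64 against 21.4 ± 3 (-1, SE 0.15, adjusted p = 0.022). CPLX2 (1.12, SE 0.19) and UNC13A (0.99, SE 0.17) were higher and the snoRNA host gene SNHG5 lower (-0.67, SE 0.1) in SA1Q+gRNA than in SA2Q+gRNA (adjusted p = 0.038, 0.038 and 0.035).

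SA1Q against SA2Q gave 23 calls, 5 higher and 18 lower, also SCG3 (0.9, SE 0.15), TXNIP (0.68, SE 0.12), TEX19 (-1.38, SE 0.25), APOBEC3B (-1.05, SE 0.19) and TNS2 (-0.85, SE 0.15). The split was 91 higher and 108 lower with the length and GC offset and 121 and 187 by DESeq2. It was 690 and 951 in a fit of only these groups, and 384 and 573 without both libraries that stood apart. TXNIP, APOBEC3B and TNS2 overlap other genes in position, so their counts are uncertain. SA1Q+gRNA against SA2Q+gRNA gave 16, 5 higher and 11 lower (124 and 133 with the length and GC offset, 93 and 85 by DESeq2), also KLHDC8A (-1.55, SE 0.28), EFNA1 (-0.75, SE 0.12) and the cell death gene BMF (-0.73, SE 0.11). SA1+gRNA against SA2+gRNA gave 2, ADAR (2.24) and ADARB1 (-5.12), with 788 genes at an unadjusted p under 0.05. ADAR differed by 1.76 and 2.02 and ADARB1 by -4.99 and -5.27 in the first comparisons. The SA1Q against SA2Q count was 4 and 3 without SA1Q replicates 1 and 2, and 5 and 3 without SA2Q replicates 1 and 2, where 3, 3, 4 and 3 of the 13 named genes passed. With guide it was 3 without SA1Q+gRNA replicate 1, 668 without SA1Q+gRNA replicate 2 (445 higher, 223 lower), and 3 and 2 without SA2Q+gRNA replicates 1 and 2, where 3, 10, 3 and 2 of 10 passed. ADAR and ADARB1 were called in every such fit of the 3 comparisons.

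Epithelial markers were lower in SA1Q than in SA2Q, with KRT19 called (-0.45) of 11 and 5 adjusted over the list alone (median -0.43, adjusted p = 1.5e-05 by camera; adjusted p = 0.02 with an estimated correlation). The integrated stress response had 0 of 35 called by edgeR, with 14 lower and 1 higher adjusted over the list alone (median -0.19, adjusted p = 2.4e-07; adjusted p = 0.12 with an estimated correlation). All 37 ribosomal protein genes lay below 0, 0 were called, and 1 was lower adjusted over the list alone (median -0.18, adjusted p = 1.3e-08; adjusted p = 0.46 with an estimated correlation). With guide, the integrated stress response also lay lower in SA1Q, with 0 called and 10 lower and 1 higher adjusted over the list alone (median -0.19, adjusted p = 3.3e-06; adjusted p = 0.1 with an estimated correlation). Interferon-stimulated genes had 0 called there (median -0.12, adjusted p = 0.00015; adjusted p = 0.061 with an estimated correlation). Between SA1+gRNA and SA2+gRNA the unfolded protein response lay higher in SA1+gRNA with 0 called (median 0.11, adjusted p = 0.00066; adjusted p = 0.59 with an estimated correlation).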

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

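Among the tests below, the test of fibroblast RNA, the batch test of the integrated stress response, the fits without SA1Q+gRNA replicate 1 or without both libraries that stood apart, and those with libraries left out after the length and GC correction were chosen only after the results had been seen.

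SA1Q and SA2Q differed in 21 genes besides ADAR and ADARB1 without guide and in 14 with guide, by edgeR's test of the difference between the groups. These numbers depended on the spread shared by all groups. A fit of only the groups compared called 1641 genes in all without guide and 2 with guide. Without both libraries that stood apart, 957 were called without guide. Epithelial markers were lower in SA1Q than in SA2Q with an adjusted p of 0.02 with an estimated correlation (1.5e-05 at the preset correlation). This list holds KRT8 and KRT19, abundant in every library, so the result is not read as a difference in other cell types. Of 386 transcripts without a gene name that were tested apart from the comparisons above, 2 were higher and 6 lower in SA1Q than in ctrl, and 1 was higher in SA1Q+gRNA.

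The first pattern is that ctrl replicate 1 and SA1Q+gRNA replicate 1 stood apart together, and their deviations from the other replicate of their group correlated across genes with r = 0.44. A trend with transcript length and GC content as the whole cause was argued against, since r stayed at 0.43 after its correction. Spearman's rho of the deviations with length went from -0.37 in both groups to 0.06 in ctrl and 0.18 in SA1Q+gRNA. A weaker length trend of opposite sign thus remained, whereas rho with GC content became -0.01 and -0.02. Lower depth was argued against too, since r was 0.42 with every library thinned to 40.2 M counts. Fibroblast RNA as the source of COL6A3, which exceeded its mean over the other 12 libraries by 2.28 and 1.99 CPM, stays open, since COL1A2, COL3A1 and LUM together differed from theirs by -0.221 CPM in ctrl replicate 1 and 0.64 in SA1Q+gRNA replicate 1 (SD 0.27 over the 12), which goes against it, but COL1A2 alone was highest in these libraries (0.239 and 0.386 CPM against at most 0.135). RNA from other cells or from another sample, and a handling or library batch that the labels do not give, remain open, the source of the higher GRIA2 and GRIA4 was not tested, and no biological explanation was tested.

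The second pattern is the larger number of genes called in SA1Q against ctrl (459) than in SA2Q against ctrl (14), a ratio of 32.8. Where ctrl replicate 1 was left out, both counts below were measured against ctrl replicate 2 alone. The ratio was 39.4 without ctrl replicate 1, which counts against that library as the cause, but that fit kept SA1Q+gRNA replicate 1, whose spread all groups share; with the latter left out, the ratio was 29.6 (1155 and 39 genes) and then 2.14 once ctrl replicate 1 was also left out (1217 and 568), so the control library stays open as a cause. Length and GC content also cannot be told apart from it, since the ratio was 6.06 after correction and ran from 1.97 to 112 when libraries were then left out in turn. A lasting difference of the SA1Q line is consistent with 73.8% of 458 of these genes having the same sign in SA1Q+gRNA against SA2Q+gRNA (48.7% of the other genes). That share was 59.8% without SA1Q+gRNA replicate 2 and 86.7% without SA1Q+gRNA replicate 1. The deviation that ctrl replicate 1 shares with SA1Q+gRNA replicate 1 enters SA1Q against ctrl and SA1Q+gRNA against SA2Q+gRNA with opposite signs. It therefore tends to lower the share, and the 59.8% is not read as going against the line. The pattern remains only a hypothesis about the line, which may reflect the enzyme or the clone.

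The third pattern is the lower integrated stress response in both Q groups with guide than in the enzymes without the change, at the preset correlation; with an estimated one the adjusted p was 0.028 for SA1Q+gRNA but 0.28 for SA2Q+gRNA, where 0 genes were called by edgeR. Length and GC content as the whole cause of the preset-correlation calls was argued against, since the larger of their adjusted p-values was 2.6e-09 after correction and the smaller 1.2e-25. A culture or library batch shared by SA1+gRNA and SA2+gRNA cannot be told apart from the effect of the Q change, since those groups have no partner without guide. The Q and non-Q enzymes were also held by different lines, so other differences between the lines cannot be told apart from the Q change either. The list differed from ctrl at the preset correlation in 2 of the 4 Q groups, which a shift of SA1+gRNA and SA2+gRNA alone would not give, but it could still account for SA2Q+gRNA. A biological effect of the Q change remains open and untested.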

How the results depend on the processing

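Of the settings below, the halved library, the fit without both libraries that stood apart, the longest transcript, limma on FPKM, and the length and GC offset were chosen only after the data had been seen; the other tests were not. Counts are genes called, and where no cause is named the cause was not tested. Median-of-ratios size factors, halving 1 library and the longest transcript kept each gene count within 1.5 times, and no scaling moved the median of all genes by more than 0.006. Of 174 named gene results that were called, 30 kept the call under every setting, 144 lost it under at least 1, and 0 reversed. A change of pseudocount was not run, since the values were counts. Depth limits genes of few counts, and pairs of libraries limit every SD.

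Without a filter on low counts, SA2Q, SA1+gRNA, SA2+gRNA, SA1Q+gRNA and SA2Q+gRNA against ctrl gave 41, 40, 63, 271 and 30 genes. The guide comparison of SA1Q gave 1, SA1Q+gRNA against SA1+gRNA 380, SA2Q+gRNA against SA2+gRNA 15, SA1Q against SA2Q 106, and SA1Q+gRNA against SA2Q+gRNA 57. A fit of only the groups compared has fewer libraries to estimate the spread and does not share it with the other groups. There SA1Q, SA2Q, SA2+gRNA, SA1Q+gRNA and SA2Q+gRNA against ctrl gave 62, 1, 3, 3 and 2. The guide comparison of SA2Q gave 10, the Q comparisons 11 and 133, SA1Q against SA2Q 1641, SA1+gRNA against SA2+gRNA 4, and SA1Q+gRNA against SA2Q+gRNA 2. The counts of 10, 133, 1641 and 4 were rises, in comparisons that hold neither library that stood apart. SA1+gRNA against ctrl, which holds ctrl replicate 1, went from 7 to 10. With only both libraries that stood apart left out, SA2Q+gRNA against SA2+gRNA went from 2 to 119 and SA1Q against SA2Q from 23 to 957. The spread of those libraries thus held these counts down in the shared fit. SA1+gRNA against SA2+gRNA went from 2 to 4 there, and the guide comparison of SA2Q stayed at 0. The number of libraries was not tested separately.

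DESeq2 gave 1064, 91, 101, 130, 478 and 101 genes in SA1Q, SA2Q, SA1+gRNA, SA2+gRNA, SA1Q+gRNA and SA2Q+gRNA against ctrl, 589 and 57 in the Q comparisons, and 308, 9 and 178 for SA1Q against SA2Q, SA1+gRNA against SA2+gRNA and SA1Q+gRNA against SA2Q+gRNA. Without both libraries that stood apart, SA1Q, SA2Q, SA1+gRNA, SA2+gRNA and SA2Q+gRNA against ctrl gave 1217, 568, 382, 473 and 848, SA2Q+gRNA against SA2+gRNA 119, and the same contrasts of ADAR with ADARB1 constructs 957, 4 and 144. With the length and GC offset the 6 comparisons with ctrl gave 970, 160, 41, 197, 995 and 135, the Q comparisons 684 and 33, SA1Q against SA2Q 199, and SA1Q+gRNA against SA2Q+gRNA 257. Limma on log2(FPKM + 0.1) gave 6, 4, 5 and 5 in SA2Q, SA1+gRNA, SA2+gRNA and SA2Q+gRNA against ctrl, 241 in SA1Q+gRNA against SA1+gRNA, and 60 in SA1Q against SA2Q.

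No pairing of samples by replicate number was visible, since the deviations of same-numbered libraries correlated above 0.1 in 1 of 21 pairs of groups (r from -0.14 to 0.44). That pair was ctrl and SA1Q+gRNA, which hold the libraries that stood apart. A pairing with weak effects is not excluded. With the replicate block the counts were 304 in SA1Q against ctrl, 94 and 1 in the Q comparisons, 12 in SA1Q against SA2Q and 6 in SA1Q+gRNA against SA2Q+gRNA, and no other count moved by over 1.5 times.

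Leaving out 1 library at a time, where a lone library is assumed to vary like the other groups, gave 38 to 825 genes in SA1Q against ctrl, 2 to 28 in SA2Q, 4 to 22 in SA1+gRNA, 2 to 29 in SA2+gRNA, 149 to 463 in SA1Q+gRNA and 2 to 13 in SA2Q+gRNA. It gave 0 to 2114 in the guide comparison of SA1Q, 0 in that of SA2Q, 17 to 2083 and 1 to 5 in the Q comparisons, 3 to 5 in SA1Q against SA2Q and 2 to 668 in SA1Q+gRNA against SA2Q+gRNA.

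Lists called numbered 9, 4, 2 and 5 in SA1Q and SA2Q against ctrl and in the guide comparisons of SA1Q and SA2Q. With an estimated correlation they numbered 0, 1, 0 and 0, and with libraries left out in turn 8 to 12, 4 to 7, 0 to 4 and 2 to 5. Without a filter they were 7, 4 and 3 in all but the first, a fit of only the groups compared gave 4 for the guide in SA1Q, the longest transcript 7 for SA2Q, and the length and GC offset 6 for the guide in SA1Q. Without both libraries that stood apart, SA2Q against ctrl gave 8 and the guide in SA1Q 1.

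Apart from the estimated correlation, lists were run again only in SA1Q and SA2Q against ctrl, the guide comparisons, and the Q comparisons. The epithelial and interferon-stimulated lists of SA1Q+gRNA against ctrl, and the epithelial list of SA1Q against SA2Q, were not among them. In the comparisons run, the direction of a list that was called in either fit turned in 8 results. OXPHOS turned downward without ctrl replicate 2 in SA1Q (adjusted p = 0.0024 by camera) and SA2Q against ctrl (0.0047), and in SA1Q+gRNA against SA1+gRNA without both libraries that stood apart (0.05); with libraries left out in turn its adjusted p ran from 2.5e-06 to 0.88 in SA1Q and from 2.2e-11 to 0.44 in SA2Q against ctrl. Ribosomal proteins turned upward in SA2Q against ctrl without ctrl replicate 1 (0.04) and without both libraries (0.023), with a range from 3.2e-15 to 0.04 over the left-out libraries. With the length and GC offset, the guide comparison of SA1Q turned for G2 and mitosis (0.0077, upward), OXPHOS (0.029, downward) and ribosomal proteins (0.66, downward).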

Other observations

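The test of transcripts that begin with a terminal oligopyrimidine tract was chosen only after the results had been seen. So was the test of whether the change from non-Q to Q lines differed between the enzymes.

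Of 23 transcripts outside the ribosomal protein list that begin with a terminal oligopyrimidine tract, which ties their translation to growth signalling, 8 were called lower in SA1Q than in ctrl by edgeR and the other 15 were not called (median log2 change -0.19). The list was written after the results had been seen. They were the initiation factor genes EIF3F (-0.69), EIF4B (-0.5) and EIF3L (-0.43), the elongation factor genes EEF1G (-0.49) and EEF2 (-0.41), TPT1 (-0.57) and the snoRNA host genes SNHG5 (-0.81) and GAS5 (-0.58, overlapping GAS5-AS1 and uncertain). In SA1Q+gRNA 5 were lower than in ctrl (median -0.18) and 9 lower than in SA1+gRNA (median -0.27). In SA2Q against ctrl 21 of the 23 lay below 0 with 0 called (median -0.11). With an estimated correlation and adjustment over the 14 comparisons the class passed in none (smallest adjusted p = 0.2 by camera of limma). Of the genes named here, EEF1G, EIF3F, EIF3L, EEF2 and GAS5 missed the threshold without SA1Q replicate 1 (adjusted p = 0.065, 0.081, 0.068, 0.24 and 0.06, edgeR) and without SA1Q replicate 2 (0.094, 0.073, 0.075, 0.14 and 0.16). TPT1 missed it without SA1Q replicate 2 (0.055), EEF2 without ctrl replicate 2 (0.065) and GAS5 without ctrl replicate 1 (0.096).

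The class may be lower in the SA1Q line as a whole, which is a hypothesis. In SA1Q+gRNA against SA2Q+gRNA, which shares no library with SA1Q against ctrl, its median was -0.15 and the adjusted p was 0.3 with an estimated correlation (0.13 before adjustment), so the hypothesis stays open.

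The changes from non-Q to Q lines, in which line and Q change differ together, were compared between the enzymes. SA1Q+gRNA against SA1+gRNA, set against SA2Q+gRNA against SA2+gRNA, gave 0 genes called by edgeR. At an unadjusted p under 0.05 there were 1544, and the smallest adjusted p was 0.24. These changes correlated across genes with r = 0.16.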
